A study of Homo sapiens with 6 samples.

How the data were processed

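RNA sequencing libraries were made from T24 and UM-UC-3, both established human bladder carcinoma cell lines. Per the labels, cells of each line were treated for 48 h with a negative control, with siRNA-1 or with siRNA-2, and each of these gave 1 library, so that 6 libraries formed 4 groups. The labels do not make clear whether the negative control was itself an siRNA, so a difference from it may include the effect of siRNA exposure. RNA was extracted with Trizol and purified on Qiagen columns, and paired-end reads were taken on an Illumina instrument, per the labels' protocols. Whether RNA with a poly(A) tail was selected, and whether the kit kept the strand, is not given in the sources used here. The labels do not name the target of the siRNAs. The series title and the column names of the UM-UC-3 files name HSF1.

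The submitters' processing notes name HISAT2 2.1.0, HTSeq 0.6.1 and bcl2fastq 2.19.1 and the builds hg19 and GRCh37, without giving their roles. The values deposited by the authors were CPM, reads scaled to the gene-assigned reads of each library, per the file headers and the values. In each library 100% of the values were whole multiples of 1 read's worth of CPM within a tolerance of 0.01, with 0.5 read standing for a count of 0, so whole reads were recovered. Library totals were 23709089, 27634857 and 26746754 reads for T24 control, siRNA-1 and siRNA-2, and 24995420, 27282437 and 28504833 for UM-UC-3 in the same order. At these depths 1 read was worth 0.0351 to 0.0422 CPM. Each deposited file listed the genes of a comparison of the control with 1 siRNA, either at 1 read or more in both libraries or at 5 reads or more in one when the other had 0. Where a gene was listed in the file of 1 siRNA of a line and not in that of the other, its missing value was at most 4 reads and was set to 0, for 3410 values in T24 and 4104 in UM-UC-3. The omitted genes held at most 0.0207% of the reads of a library.

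Genes were joined by their Ensembl identifiers, because 4244 genes had different names in the files of the lines, and 24 names that a spreadsheet had turned into dates were restored. T24 files listed 22793 genes and UM-UC-3 files 23987, with 19945 in both lines. Gene names, gene types and transcript sequences came from GENCODE annotation of another build than the one in the processing notes, so it was matched by identifier alone and no coordinate is given. Genes with near-identical copies, among them histone, ribosomal protein, keratin, HSPA1A, HSPA1B and mitochondrial genes, are uncertain where the counting could have split or dropped their reads, and genes that overlap on opposite strands could not be separated.

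The design fixed before the data were examined named edgeR's quasi-likelihood test with TMM scaling for read counts, and limma-trend for FPKM or TPM alone. The files held CPM, so limma-trend was run on log2(CPM + 1), with genes at a mean of at least 1 CPM, Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change is therefore on the log2(CPM + 1) scale, which understates the change of low genes. The comparisons, the gene lists and their test, the rule for naming genes and the first group of other settings below were chosen before the data were examined. The comparison over both lines used all 6 libraries with the cell line as a covariate. The comparisons within a line and their difference came from 1 fit of 4 group means, in which the single control of a line was assumed to vary like the siRNA libraries. The comparison of siRNA-2 with siRNA-1 came from a fit with 3 treatments and the cell line. There were 13265 genes tested in both lines, 13584 in T24 and 13696 in UM-UC-3. Nothing in the labels says that the libraries came from separate cultures, so p-values measure only the spread between these libraries. Part of it may be technical. In the fit of 4 group means that spread is the difference between siRNA-1 and siRNA-2 within each line. Over both lines it also holds differences between the lines in the siRNA effect.

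The 32 gene lists were tested with camera at its preset correlation of 0.01, adjusted over the 31 lists with at least 3 tested members, and beside it with camera at an estimated correlation and with fry. Fold changes of single libraries carry 95% intervals from an exact binomial interval of the reads, and intervals of a level are exact Poisson intervals. These intervals cover counting error only.

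The genes named were HSF1, PRMT5 and WDR5, then up to 12 higher and 12 lower over both lines, 6 and 6 within a line and 4 and 4 for the differences. They were taken by the size of the fold change among genes past the threshold with a symbol, a mean of at least 50 reads and, except for the differences, the same direction in each siRNA library. Where fewer than 5 genes (4 for the differences) qualified, genes with the smallest p were added and are said not to pass. Up to 4 members of each list were taken by their p over both lines. Some genes that this rule takes are not reported here. Other genes named in the text were chosen after their values were seen.

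The first group of other settings was quantile normalization, a pseudocount of 0.1, no filter, a mean of at least 5 CPM, a fit of 4 groups, a term for the siRNA number, each library left out in turn, and another correlation for the lists. Added after the data were seen were edgeR's quasi-likelihood test with TMM or RLE scaling, DESeq2 and limma-voom on the recovered reads. The edgeR test with TMM was the one the design had named for read counts. Also added then were the removal of genes with 2 short words in the 3' UTR and a term for the siRNA number within each line. For the lists, that term, quantile normalization and a pseudocount of 0.1 were added. With the siRNA term the spread within a line or for the difference comes from the part of the difference between the siRNAs that the lines do not share. Without that term the fits left 3 residual degrees of freedom over both lines and 2 within a line or for the difference. The term leaves fewer, so small p-values under it rest on very little spread and on 1 control per line. Without the control of a line, the comparison over both lines gives the fold change of the other line alone. For the short words the longest annotated 3' UTR of each of 10073 genes at a mean of at least 5 CPM was searched for words of 7 bases, with length and GC content of the UTR taken out. Correlations of fold changes were set beside 20 simulated tables of unchanged groups against the same controls.

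The procedures were tested on simulated data. At a biological coefficient of variation of 0.3, the comparison over both lines called 91.3% of genes changed 4-fold and 20% of those changed 2-fold, on 13134 genes. The comparison within T24 called 41.7% of the 4-fold genes (13116 genes), that within UM-UC-3 43.8% (13137 genes), the difference between lines 6% (13130 genes) and siRNA-2 against siRNA-1 68% (13149 genes). A changed gene had the same fold in each library that carried the change. These shares thus leave out differing effects of the siRNAs or lines, and may overstate what could be called in the data. In 20 tables with 1 list lowered 1.4-fold, camera called that list in 20 and called 0 of 580 other lists. Genes were drawn independently there, so this count does not cover lists whose members move together. In the data the estimated correlation over both lines was 0.25 for the S phase list, 0.517 for mitosis and 0.767 for the ATF4 and integrated stress response list. The word search ranked a lowered word 1 in 20 of 20 tables of 10073 genes, and in 0 of 20 permuted tables did the top word of a line reach the top 10 of the other line. R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.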

Results

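Expression of 19945 genes listed in both lines was measured in 6 libraries of the bladder carcinoma lines T24 and UM-UC-3, each treated for 48 h with a negative control, siRNA-1 or siRNA-2. Each combination of line and treatment was 1 library, of 23709089 to 28504833 gene-assigned reads. The 4 siRNA libraries were set against the 2 controls, within each line and over both lines, to ask which genes depend on the silenced factor. The title of the series names HSF1, the transcription factor that drives heat shock genes, together with the arginine methyltransferase PRMT5 and WDR5, a scaffold of histone H3K4 methyltransferase complexes, in the spread of bladder cancer through lymphatic vessels.

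HSF1 (ENSG00000185122) was lower than the control in each of the 4 siRNA libraries. In T24 it stood at 106 CPM in the control, 20.3 with siRNA-1 and 22.7 with siRNA-2, and in UM-UC-3 at 138, 50.3 and 36.5 CPM. The siRNA libraries thus held 19.1% and 21.3% of the control in T24 (95% counting intervals of the ratio 0.174 to 0.21 and 0.195 to 0.233) and 36.6% and 26.6% in UM-UC-3 (0.343 to 0.389 and 0.247 to 0.285). Over both lines the log2 fold change was -1.96 ± 0.26 (SE), with an unadjusted p of 4.1e-05 in limma-trend that did not pass after adjustment over all genes (adjusted p = 0.424). DESeq2 on the recovered reads gave -2.04 (adjusted p = 8.22e-07). PRMT5 (ENSG00000100462) stood at 40.6, 73.1 and 47.4 CPM in T24 and 56.1, 57.0 and 56.2 CPM in UM-UC-3, in the order control, siRNA-1, siRNA-2 (log2 fold change over both lines 0.27 ± 0.26, adjusted p = 0.759). WDR5 (ENSG00000196363) stood at 111, 144 and 164 CPM in T24 and 146, 152 and 137 CPM in UM-UC-3 (0.23 ± 0.22, adjusted p = 0.76). Without the T24 control, which leaves the fold change of UM-UC-3 alone, the WDR5 value was -0.012.

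**Figure D1:**
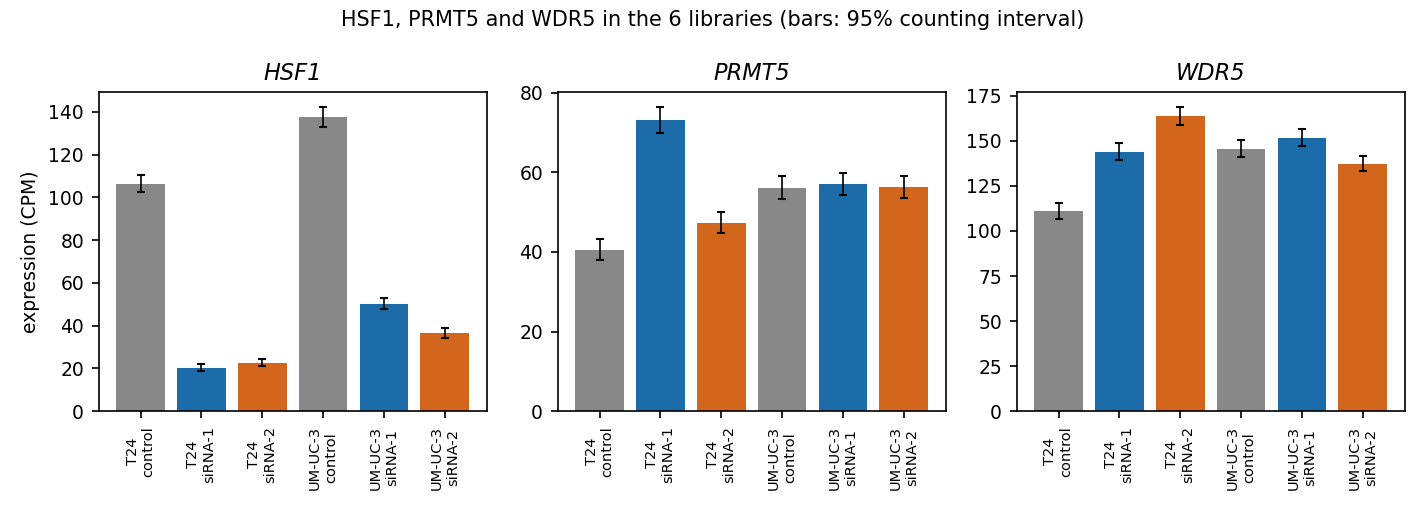
Expression of HSF1, PRMT5 and WDR5 in CPM (vertical axes) in the control, siRNA-1 and siRNA-2 libraries of T24 and UM-UC-3, with 95% Poisson counting intervals as error bars. HSF1 lay at 20.3 to 50.3 CPM in the siRNA libraries and at 106 and 138 CPM in the controls.

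Genes of DNA replication and cell division fell together over both lines, by limma's camera test. All 38 tested members of the S phase and DNA replication list had a negative log2 fold change, with a median of -0.82 (adjusted p = 1.36e-29, and adjusted p = 0.436 with an estimated correlation). None of the 38 passed over all genes and 25 passed adjusted over the list alone. CDC45, a part of the replicative helicase, had -1.34 ± 0.29 (SE), the flap endonuclease FEN1 -1.04 ± 0.23, thymidine kinase TK1 -1.01 ± 0.22 and the cell cycle transcription factor E2F2 -1.36 ± 0.30, each lower in 4 of 4 siRNA libraries. All 33 members of the mitosis list were also negative, with a median of -0.85 (adjusted p = 4.69e-25, and adjusted p = 0.436 with an estimated correlation), and 27 of them passed adjusted over the list alone against 0 over all genes. They included the cyclin-dependent kinase CDK1 (-1.36 ± 0.31), the spindle kinase AURKA (-1.29 ± 0.34), the microtubule depolymerase KIF2C (-1.10 ± 0.25) and the securin PTTG1 (-0.88 ± 0.22). Of 23 homologous recombination and Fanconi genes 20 were negative (median -0.67, adjusted p = 4.06e-10, and adjusted p = 0.436 with an estimated correlation), 7 of them past the threshold adjusted over the list alone and 0 over all genes. RAD54L, a motor protein of strand exchange, had -1.26 ± 0.28 and FANCI, a part of the crosslink repair complex, -0.96 ± 0.26. These 3 lists kept their calls without each of the 6 libraries in turn.

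Histone genes rose over both lines while the replication genes fell. All 9 measured members of the replication-dependent histone list, whose transcripts usually lack a poly(A) tail, were positive, with a median log2 fold change of 1.32 (adjusted p = 1.5e-07, and adjusted p = 0.436 with an estimated correlation). Of the 9, 6 passed adjusted over the list alone and 0 over all genes. HIST1H2AC stood at 22.9, 133 and 54.6 CPM in T24 control, siRNA-1 and siRNA-2 and at 11.7, 43.9 and 65.3 CPM in UM-UC-3. HIST1H2BC stood at 4.68, 22.1 and 21.3 CPM in T24 and 1.52, 3.665 and 7.05 CPM in UM-UC-3. Histone genes are near copies of each other, so the share of reads each received is uncertain. The call was kept without each of the 6 libraries in turn.

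Heat shock factor targets, chaperones that fold proteins in the cytosol and the nucleus, fell by a smaller amount. Of 28 members 24 were negative, with a median of -0.28 (adjusted p = 0.000113, and adjusted p = 0.436 with an estimated correlation), and 0 passed either over all genes or adjusted over the list alone. The smallest p were those of HSP90AA1, the stress-inducible HSP90 (log2 fold change -0.83 ± 0.23), and the chaperone cofactor HSPH1 (-0.70 ± 0.23), while HSP90AB1 (-0.72) was at 3429 CPM in the T24 control and 3773 CPM in T24 siRNA-2. HSPA1A stood at 86.6, 81.4 and 51.2 CPM in T24 and 10.6, 10.8 and 10.1 CPM in UM-UC-3, and DNAJB1 at 113, 113 and 72.7 CPM and 92.6, 79.2 and 61.0 CPM. HSPA1A and the HSP90 genes have near copies, so their values are uncertain. Matrix proteases and their inhibitors, which degrade extracellular matrix, also fell, with 11 of 15 negative and a median of -0.25 (adjusted p = 0.00191, and adjusted p = 0.436 with an estimated correlation). The plasminogen activators PLAT (-1.33 ± 0.30) and PLAU (-0.92 ± 0.27) and the gelatinase MMP9 (-0.97 ± 0.34) had the smallest p, and 1 member passed adjusted over the list alone against 0 over all genes. Both lists kept their calls without each of the 6 libraries in turn.

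A further 7 lists had a call below 0 over both lines. Without the T24 control, which leaves the fold change of UM-UC-3 alone, each of these 7 lists lost its call. They were the ATF4 and integrated stress response list, which covers amino acid synthesis and stress genes (median -0.62, adjusted p = 4.74e-09), the endoplasmic reticulum unfolded protein response (-0.68, 3.49e-07), the AP-1 and immediate early genes (-0.51, 1.26e-05), NF-kB targets and cytokines (-0.77, 2.34e-05), the interferon response (-0.41, 0.0036), the heat shock factor family (-0.21, 0.0179) and the lymphangiogenesis list (-0.29, 0.0243). With an estimated correlation the adjusted p was 0.477, 0.47, 0.468, 0.468, 0.572, 0.468 and 0.572 in the same order. Adjusted over the list alone 0 members passed in the first 5 lists and 1 in each of the last 2, NRP2 in the lymphangiogenesis list and HSF1 in its family, against 0 over all genes. The heat shock factor family list holds HSF1 itself (-1.96), beside HSF4 at -0.21 (adjusted p = 0.82) and HSF2 at -0.08 (adjusted p = 0.936), so its call is no sign that the family changed apart from HSF1. NRP2, a co-receptor of lymphatic growth factors, stood at 14.8, 1.92 and 2.13 CPM in T24 and 12.6, 6.12 and 7.61 CPM in UM-UC-3, and VEGFC, the main lymphatic growth factor, at 31.0, 19.2 and 8.97 CPM and 18.5, 27.9 and 26.8 CPM. Without the T24 control the ATF4 list (adjusted p = 0.556), the interferon list (0.288) and the lymphangiogenesis list (0.644) turned upward, and the unfolded protein (0.942), NF-kB (0.18), AP-1 (0.108) and heat shock factor family (0.0985) lists stayed downward. Without T24 siRNA-1 the lymphangiogenesis call was lost as well (0.335), and without T24 siRNA-2 the calls of the interferon list (0.21) and of the heat shock factor family (0.0636).

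The genes with the smallest p and the same direction in 4 of 4 siRNA libraries did not pass the threshold (adjusted p = 0.424 for each). FAM210B, a mitochondrial protein, was at 1.55 ± 0.26 (SE) on the log2 scale, PRKAR1B, a regulatory subunit of protein kinase A, at 1.32 ± 0.24, the H3K27 demethylase KDM6B at 1.41 ± 0.27, HIST1H2AC at 1.98 ± 0.36 and HIST1H2BC at 1.64 ± 0.31. On the lower side, beside HSF1, stood the carbonic anhydrase CA2 (-1.91 ± 0.31), the clathrin adaptor HIP1 (-1.52 ± 0.30), the secretory GTPase RAB27B (-1.63 ± 0.33) and the mitotic kinase PBK (-1.12 ± 0.23). A change of at least 2-fold in 4 of 4 siRNA libraries was seen for 9 genes, 5 higher (FAM210B, PRKAR1B, HIST1H2AC, HIST1H2BD and AC048341.1) and 4 lower (HSF1, RAB27B, CA2 and CELSR2). Simulated unchanged groups against the same controls gave a mean of 0.65 such genes and at most 2. In all, 2496 genes were higher and 1613 lower in 4 of 4 siRNA libraries. This was 31% of 13265 genes, against 22.2% (range 21.7 to 23) in the simulation. The simulated lines varied independently, so the simulation holds no effect of a single siRNA that the lines share. It also holds no shift of all genes against the control. In the data the median log2 fold change of all genes over both lines was 0.061, against 0.002 by edgeR with TMM scaling. A shared effect of a single siRNA would also raise these counts, and a shift above 0 would raise that of higher genes. The excess is thus not by itself a sign of a change common to both siRNAs. By limma-trend 0 genes passed, with 1313 at an unadjusted p under 0.05 (682 higher, 631 lower). edgeR with TMM or RLE scaling and limma-voom also called 0, and DESeq2 called 78, of which 31 were higher and 47 lower.

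**Figure D2:**
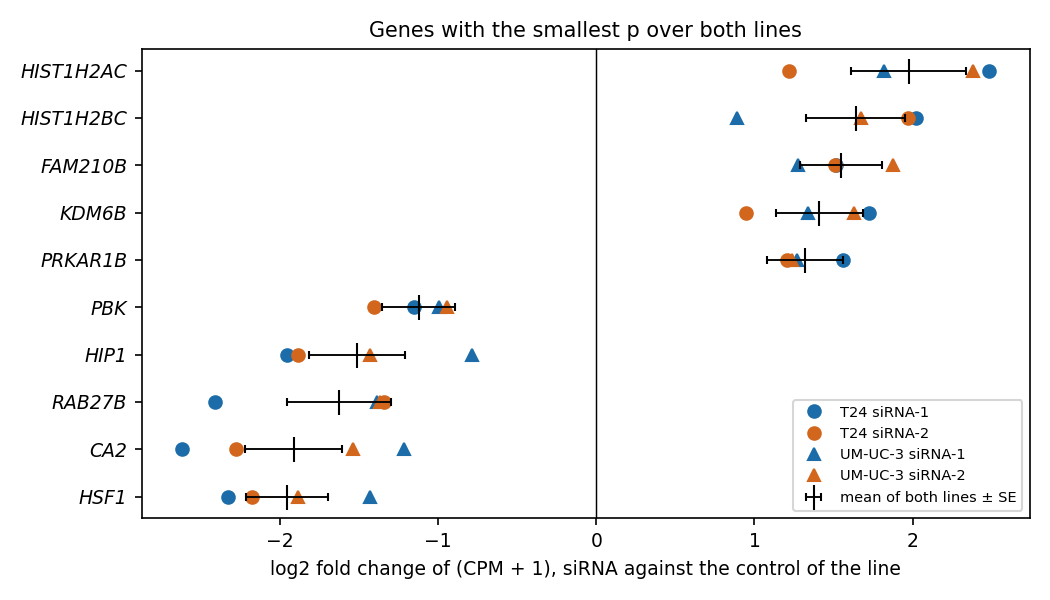
Log2 fold change of (CPM + 1) against the control of the line (horizontal axis) for the 5 higher and 5 lower genes with the smallest p over both lines, with points for the 4 siRNA libraries and the mean of both lines ± SE as black bars. All 4 points of a gene lie on the same side of 0, and HSF1 has a mean of -1.96.

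The other 18 lists tested over both lines were not called. Among those on epithelial identity and adhesion, the median was -0.16 for mesenchymal genes (adjusted p = 0.108), -0.04 for epithelial genes (0.291), -0.16 for urothelial markers (0.189), -0.05 for integrins and focal adhesion genes (0.195), 0.15 for the LY6/uPAR family (0.678) and -0.18 for hyaluronan and glycosaminoglycan synthesis (0.137). The median was 0.19 for the PRMT5 complex and arginine methyltransferases (0.106) and -0.01 for the WDR5 and MLL/SET1 complexes (0.379). It was -0.01 for p53 targets (0.387), 0.15 for hypoxia and glycolysis (0.375), -0.02 for cholesterol synthesis (0.411), -0.17 for NRF2 targets (0.0818) and 0.24 for autophagy and lysosome genes (0.0537). It was 0.10 for the proteasome (0.365), -0.04 for cytosolic ribosomal proteins (0.291) and 0.16 for mitochondrial DNA genes (0.156). Apoptosis regulators had a median of 0.12 but a mean of -0.03 and a downward test (0.88), and the chaperonin CCT list a median of 0.10 and a mean of 0.03 with a downward test (0.928). Of the markers of blood, endothelial and fibroblast cells only PECAM1 (at most 4.08 CPM) and MYH11 (at most 2.07 CPM) reached a mean of 1 CPM, too few for a test.

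Leaving out 1 library gave calls to some of these lists, in directions that depended on the control left out. Without the T24 control the fold change is that of UM-UC-3 alone, and without the UM-UC-3 control that of T24 alone. The calls without a control thus repeat those within a line, given below, and are no separate check. Without the T24 control the chaperonin list (adjusted p = 0.00128), ribosomal proteins (0.00192), mitochondrial DNA genes (0.00294) and the proteasome (0.0222) were called lower and autophagy (0.00497) and mesenchymal genes (0.0386) higher. Without the UM-UC-3 control mitochondrial DNA genes (3.81e-06), the proteasome (0.00202), the PRMT5 list (0.0138) and the chaperonin list (0.0266) were called higher and mesenchymal genes lower (5.17e-05). Autophagy genes were called higher without T24 siRNA-1 (0.0285), NRF2 targets lower without T24 siRNA-2 (0.00731) and mesenchymal genes lower without UM-UC-3 siRNA-1 (0.0211). The PRMT5 list (0.0195) and mitochondrial DNA genes (0.0253) were called higher without UM-UC-3 siRNA-2.

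**Figure D3:**
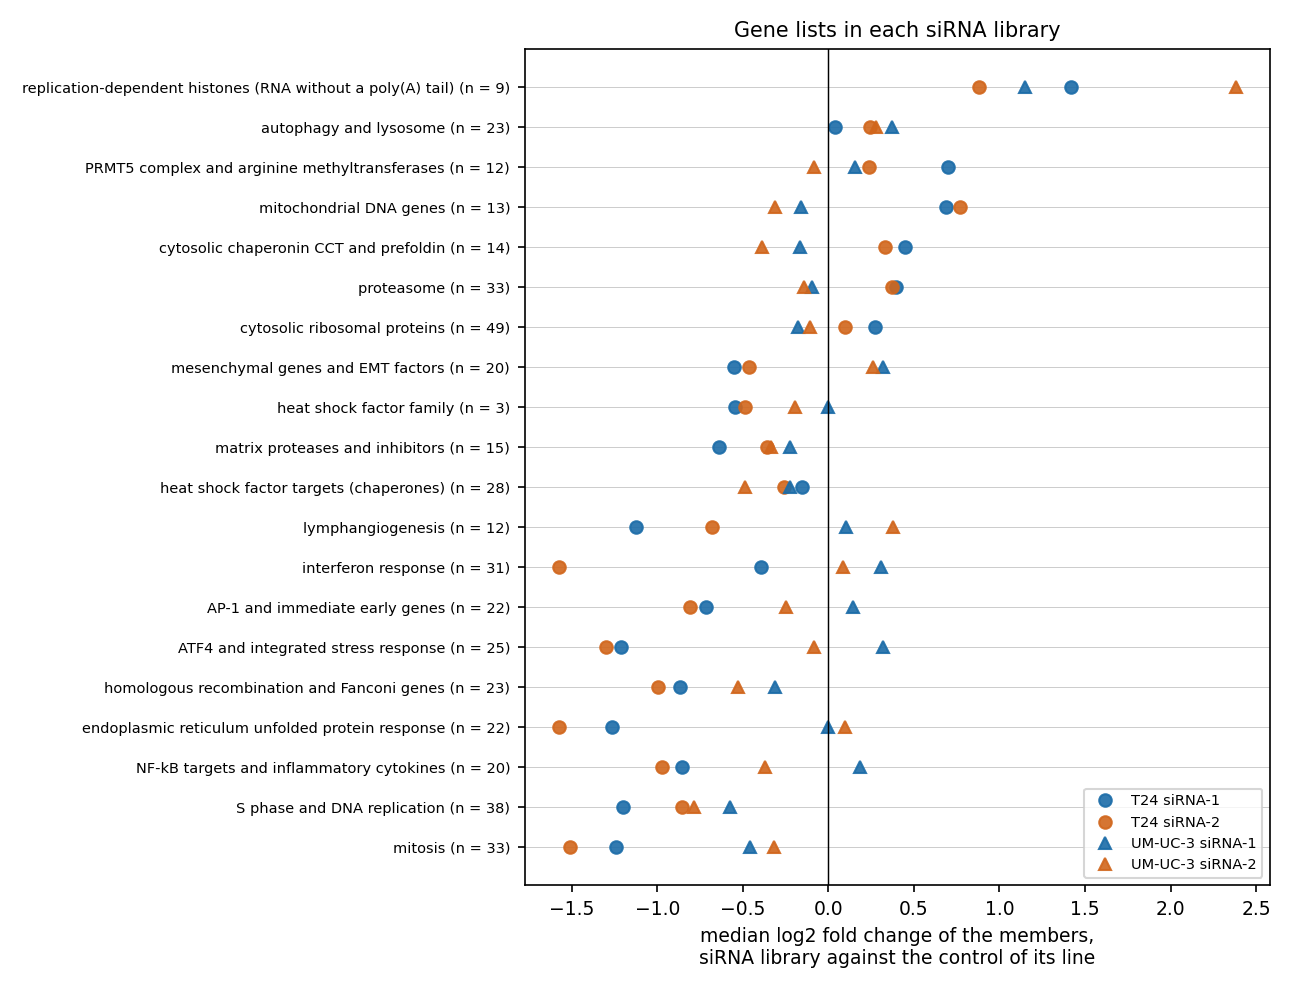
Median log2 fold change of the members of 20 gene lists (horizontal axis) in each siRNA library against the control of its line, with T24 as circles and UM-UC-3 as triangles. The S phase, mitosis and recombination lists lie below 0 and the histone list above 0 in 4 of 4 libraries, and the ATF4 list lies at -1.21 and -1.30 in T24 and at 0.32 and -0.09 in UM-UC-3.

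Within T24 the siRNA libraries had lower levels of stress, secretory and antiviral genes as well as of cell cycle genes. All 25 ATF4 and integrated stress response genes were negative (median -1.17, adjusted p = 6.63e-19, and adjusted p = 0.287 with an estimated correlation), and 19 passed adjusted over the list alone. CHAC1, which degrades glutathione, stood at 141, 26.5 and 17.3 CPM in the control, siRNA-1 and siRNA-2, and asparagine synthetase ASNS at 12.4, 1.38 and 1.83 CPM. Of 22 unfolded protein response genes 20 were negative (median -1.38, adjusted p = 1.58e-13, and adjusted p = 0.287 with an estimated correlation), 15 of them past the threshold adjusted over the list alone. HSPA5, the main chaperone of the endoplasmic reticulum, stood at 6698 CPM in the control and at 2138 and 2167 CPM with the siRNAs. Of 31 interferon response genes 21 were negative (median -0.84, adjusted p = 2.05e-08, and adjusted p = 0.439 with an estimated correlation), with 13 past the threshold adjusted over the list alone. The interferon median was -0.39 with siRNA-1 and -1.58 with siRNA-2. IFIT2, an antiviral protein that binds viral RNA, stood at 276, 27.0 and 10.3 CPM, and OASL at 101, 3.62 and 0.523 CPM. None of these genes passed over all genes.

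Other lists that fell within T24 were mitosis (median -1.35, adjusted p = 3.81e-24), S phase (-1.01, 6.42e-18), homologous recombination (-0.89, 5.89e-08), AP-1 (-0.68, 1.45e-06), NF-kB (-0.89, 1.51e-06), mesenchymal genes (-0.41, 5.37e-05), lymphangiogenesis (-0.82, 0.000136), matrix proteases (-0.37, 0.0257), the heat shock factor family, HSF1 included (-0.52, 0.0257), and heat shock targets (-0.28, 0.0366). The adjusted p with an estimated correlation ranged from 0.287 for mitosis and mesenchymal genes to 0.463 for AP-1, matrix proteases and heat shock targets. Adjusted over the list alone 28, 14, 10, 8, 7, 2, 1, 0, 1 and 0 members passed in the order given, against 0 over all genes. The immediate early factor EGR1 stood at 594, 80.0 and 46.6 CPM and FOS at 213, 11.3 and 5.12 CPM. Lists that rose were the mitochondrial DNA genes (median 0.63, adjusted p = 3.67e-06, and adjusted p = 0.287 with an estimated correlation), the proteasome (0.30, 0.00207, and 0.439), the histones (1.11, 0.00582, and 0.463), the PRMT5 complex and arginine methyltransferases (0.44, 0.0139, and 0.57) and the chaperonin CCT list (0.37, 0.0257, and 0.463). Adjusted over the list alone 3, 0, 1, 0 and 0 members passed. PRMT6, which methylates histone H3, stood at 19.4, 65.5 and 43.0 CPM, and PRMT2, another methyltransferase, at 114, 185 and 140.5 CPM. Reads of mitochondrial genes made up 1.85% of the T24 control and 2.75% and 2.71% of the siRNA libraries. Without siRNA-1 the calls of the PRMT5 list (adjusted p = 0.229), matrix proteases (0.4) and histones (0.061) were lost, and without siRNA-2 those of the proteasome (0.0859), the chaperonin list (0.0859), the heat shock factor family (0.11) and heat shock targets (0.167). The heat shock target call was also lost without UM-UC-3 siRNA-1 (0.0531) or siRNA-2 (0.0525) and with a term for the siRNA (0.0632), under which integrins were called lower (0.0298), and that of the chaperonin list without genes with either 3' UTR word (0.053). Without T24 siRNA-2 the NRF2 (0.00402), integrin (0.011) and urothelial marker (0.0426) lists were called lower. Apoptosis regulators in T24 had a median of 0.08, a mean of -0.12 and a downward test (0.602).

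Of single genes, IFI44 (-3.67 ± 0.33, SE) and PMAIP1, an inducer of apoptosis (-3.34 ± 0.36), had among the smallest p within T24, together with the connective tissue growth factor CTGF (-2.94 ± 0.30), the receptor ADGRL4 (-2.85 ± 0.29) and the keratin KRT17, which held 326 reads in the control and 1 read in each siRNA library. IFI44, CTGF, ADGRL4, KRT17 and PMAIP1 each had an adjusted p of 0.13. On the higher side the transporter SLC16A9 stood at 7.13, 71.8 and 62.9 CPM (adjusted p = 0.13), and MT-ND6 (2.31 ± 0.29, adjusted p = 0.143) and MT-ND5 (1.72 ± 0.26, adjusted p = 0.165), subunits of complex I, were followed by RAB5IF (2.42 ± 0.40, adjusted p = 0.194). By limma-trend 0 of 13584 genes passed, with 1628 at an unadjusted p under 0.05. edgeR with either scaling and limma-voom called 0, and DESeq2 called 256, of which 34 were higher and 222 lower. With limma-trend 75 genes passed without T24 siRNA-1 and 447 without T24 siRNA-2, in fits whose spread came from the UM-UC-3 siRNA libraries alone. With a term for the siRNA, which the lines have in common, 847 of 13265 genes listed in both lines passed (220 higher, 627 lower), among them IFI44, CTGF and PMAIP1 (adjusted p = 1.01e-06 each), and SLC16A9 (2.19e-05).

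Within UM-UC-3 replication genes were lower and histone genes higher, while the ATF4, unfolded protein and interferon lists were not called. S phase genes fell, with 38 of 38 negative and a median of -0.69 (adjusted p = 3.17e-23, and adjusted p = 0.45 with an estimated correlation), as did mitosis (median -0.40, adjusted p = 4.65e-11, and 0.45), homologous recombination (-0.40, 6.08e-06, and 0.45) and heat shock targets (-0.35, 3.48e-05, and 0.45). MCM2, a subunit of the replicative helicase, stood at 370, 199 and 183 CPM and the sliding clamp PCNA at 416, 233 and 202 CPM. The chaperonin CCT list (-0.29, adjusted p = 0.00147), cytosolic ribosomal proteins (-0.18, 0.00233), mitochondrial DNA genes (-0.31, 0.00391), matrix proteases (-0.30, 0.0106) and the proteasome (-0.11, 0.0229) fell, with an adjusted p of 0.45 to 0.539 with an estimated correlation. Mitochondrial genes held 5.79%, 5.74% and 4.70% of the reads in the control, siRNA-1 and siRNA-2 libraries. Histones rose (median 1.54, adjusted p = 3.7e-10), as did autophagy and lysosome genes (0.34, 0.00495) and mesenchymal genes (0.27, 0.0371), each with an adjusted p of 0.45 with an estimated correlation. Adjusted over the list alone 5 histone genes passed and 0 in the other 11 called lists, against 0 over all genes in each of the 12. The heat shock factor family had a median of 0.01, a mean of -0.52 and a downward test (adjusted p = 0.0962). The epithelial, unfolded protein, p53, integrin and LY6/uPAR lists, with medians of 0.02, 0.03, 0.05, 0.04 and 0.03, had a downward test (adjusted p of 0.643 to 0.935), as had the PRMT5 list with a median of -0.02 and a mean of 0.01.

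Several of these calls rested on 1 library. Without siRNA-1 the ribosomal (adjusted p = 0.0923), autophagy (0.122) and mesenchymal (0.18) calls in UM-UC-3 were lost and the NF-kB (4.56e-05), AP-1 (0.000282) and heat shock factor family (0.0491) lists were called lower. Without siRNA-2 the chaperonin (0.0768) and proteasome (0.169) calls were lost and the ATF4 (0.00664), interferon (0.0195) and cholesterol synthesis (0.0105) lists were called higher. Under quantile normalization the ribosomal (0.132), mesenchymal (0.0895), proteasome (0.0855) and matrix protease (0.0504) lists kept their direction but not their call. The mesenchymal call was lost too at a mean of at least 5 CPM (0.0667) and with a pseudocount of 0.1 (0.0507).

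Single genes with the smallest p in UM-UC-3 were HIST1H4H (3.25 ± 0.46, SE), the tropomyosin TPM4 at 360, 1079 and 1003 CPM, the mTOR inhibitor DDIT4 at 25.5, 72.8 and 79.7 CPM, PPP1R3C, a regulator of glycogen synthesis, at 22.0, 92.1 and 224 CPM, and RPS15 at 85.4, 277 and 208 CPM. Lower were FP236383.3 (-3.16 ± 0.40), HSF1 (-1.66 ± 0.34), the nuclear envelope gene SYNE3 (-1.39 ± 0.32), the synaptic gene UNC13A (-1.84 ± 0.44) and AP000648.3 (-1.46 ± 0.36). FP236383.3, AP000648.3 and RPS15 have or may have near copies and are uncertain. None passed (adjusted p = 1 for each). By limma-trend 0 of 13696 genes passed, with 435 at an unadjusted p under 0.05, edgeR with either scaling and limma-voom called 0, and DESeq2 called 3 (2 higher, 1 lower). With a term for the siRNA 12 genes passed (8 higher, 4 lower), among them HIST1H4H and FP236383.3 (adjusted p = 0.00029 each), PPP1R3C (0.0048), TPM4 (0.024) and HSF1 (0.0423), and the heat shock factor family was called lower too (0.0476).

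The effect of the siRNAs differed between the lines in 15 lists when the difference itself was tested (10 with UM-UC-3 above T24, 5 below). The ATF4 list had a median difference of 1.25 (adjusted p = 1.86e-18), the unfolded protein list 1.41 (5.43e-13), mitosis 0.96 (8.22e-12), interferon 0.95 (5.33e-11), mesenchymal genes 0.88 (3.69e-07), lymphangiogenesis 1.18 (6.68e-05), NF-kB targets 0.70 (0.000245), AP-1 0.56 (0.000433), recombination genes 0.52 (0.0114) and S phase 0.36 (0.0156). Mitochondrial DNA genes had -0.92 (1.97e-10), the proteasome -0.49 (1.19e-05), the chaperonin list -0.65 (5.15e-05), ribosomal proteins -0.25 (0.00843) and the PRMT5 list -0.55 (0.0142). The adjusted p with an estimated correlation ranged from 0.361 to 0.611 for these lists. Adjusted over the list alone 12 interferon, 9 ATF4, 8 unfolded protein, 4 AP-1, 3 NF-kB, 2 mesenchymal and 2 mitochondrial genes passed and 0 in the other 8, against 0 over all genes. IFI44 stood at 85.0, 5.43 and 6.13 CPM in T24 and at 21.04, 18.0 and 18.2 CPM in UM-UC-3, and DDIT4 at 131, 27.8 and 26.7 CPM in T24 and 25.5, 72.8 and 79.7 CPM in UM-UC-3 (log2 difference 3.77 ± 0.43, adjusted p = 0.732).

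The matrix protein FN1 stood at 1481, 190 and 238 CPM in T24 and 7.96, 14.0 and 10.95 CPM in UM-UC-3, and CTGF at 531, 69.6 and 66.5 CPM and 168, 225 and 177 CPM. With a difference below 0 were FP236383.3, MT-ND6, the microtubule protein MAP1A (-2.44 ± 0.48) and SLC16A9, none of which passed (adjusted p of 0.74 to 0.836). By limma-trend 0 genes passed for the difference, with 622 at an unadjusted p under 0.05, edgeR with either scaling and limma-voom called 0, and DESeq2 called 31 (28 higher, 3 lower). With a term for the siRNA 119 genes passed (108 higher, 11 lower), among them DDIT4 (adjusted p = 7.63e-05), CTGF (0.000126), FN1 (0.000178), IFI44 (0.00077), MT-ND6 (0.00345) and SLC16A9 (0.0347). Under that term 18 lists were called, with histones (0.0321), integrins (0.0465) and cholesterol synthesis (0.0465) added to the 15. Without T24 siRNA-1 the S phase (adjusted p = 0.368) and PRMT5 (0.289) calls were lost, and without T24 siRNA-2 the ribosomal call (0.139). Without UM-UC-3 siRNA-1 the S phase (0.32), recombination (0.161), ribosomal (0.0907) and AP-1 (0.0853) calls were lost, and without UM-UC-3 siRNA-2 the PRMT5 call (0.1). The histone list was called without T24 siRNA-1 (0.013) or UM-UC-3 siRNA-1 (0.0022), integrins without T24 siRNA-2 (0.00942) or UM-UC-3 siRNA-2 (0.045) and cholesterol synthesis without UM-UC-3 siRNA-2 (0.00224). Matrix proteases (median -0.07, mean 0.07, upward test), hyaluronan synthesis (-0.07, 0.02, upward) and the WDR5 list (0.02, -0.01, downward) differed in sign and were not called.

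The fold changes of the lines were weakly correlated across 13265 genes, which are not independent replicates. The mean effect of both siRNAs in T24 and in UM-UC-3 had a Pearson r of 0.243 and a Spearman rho of 0.229, with 57.6% of genes on the same side against 50% in simulated unchanged groups. For the same siRNA in both lines r was 0.363 (siRNA-1) and 0.213 (siRNA-2), and for different siRNAs 0.097 and 0.103. Within a line siRNA-1 and siRNA-2 share 1 control library, which alone gave a simulated r of 0.5 in T24 and 0.502 in UM-UC-3. The observed r was 0.572 and 0.578, and the covariance 0.279 against a simulated 0.2124 in T24 and 0.114 against 0.0867 in UM-UC-3.

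The siRNAs differed from each other at the same genes in both lines. Comparing siRNA-2 with siRNA-1, limma-trend called 37 genes, 19 higher and 18 lower with siRNA-2. Higher were the endosomal sorting protein SNX3 (2.45 ± 0.36, SE, adjusted p = 0.0298), the transcription factor SOX4 (2.35 ± 0.42, adjusted p = 0.0468) and CCDC106 (2.23 ± 0.40, adjusted p = 0.0468). SNX3 stood at 249 CPM in the T24 control, 29.1 with siRNA-1 and 293 with siRNA-2, and at 255.6, 80.1 and 248 CPM in UM-UC-3. Lower with siRNA-2 were the histone demethylase KDM1B (-2.26 ± 0.31, adjusted p = 0.0298), PLPBP, a binding protein of vitamin B6 (-2.25 ± 0.32, adjusted p = 0.0298), the lysosomal protein GPR137B (-2.22 ± 0.37, adjusted p = 0.0444) and the splicing factor DNAJC8 (-2.04 ± 0.26, adjusted p = 0.0298). DNAJC8 stood at 162, 231 and 48.4 CPM in T24 and 181, 183 and 49.9 CPM in UM-UC-3. CLNS1A, a partner of PRMT5, was lower with siRNA-2 as well (-2.03 ± 0.28, adjusted p = 0.0298), and so was XBP1, a transcription factor of the unfolded protein response (-1.88 ± 0.29, adjusted p = 0.0331). Without T24 siRNA-2 the comparison called 0 genes, without T24 siRNA-1 21, without UM-UC-3 siRNA-2 87, and without UM-UC-3 siRNA-1, the T24 control or the UM-UC-3 control 476, 485 and 465. No control enters the difference between the siRNAs, so leaving out a control changed only the spread that this difference was tested against. edgeR called 0 with either scaling, limma-voom 22 and DESeq2 250, and 0 genes passed without the filter on low values.

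**Figure D4:**
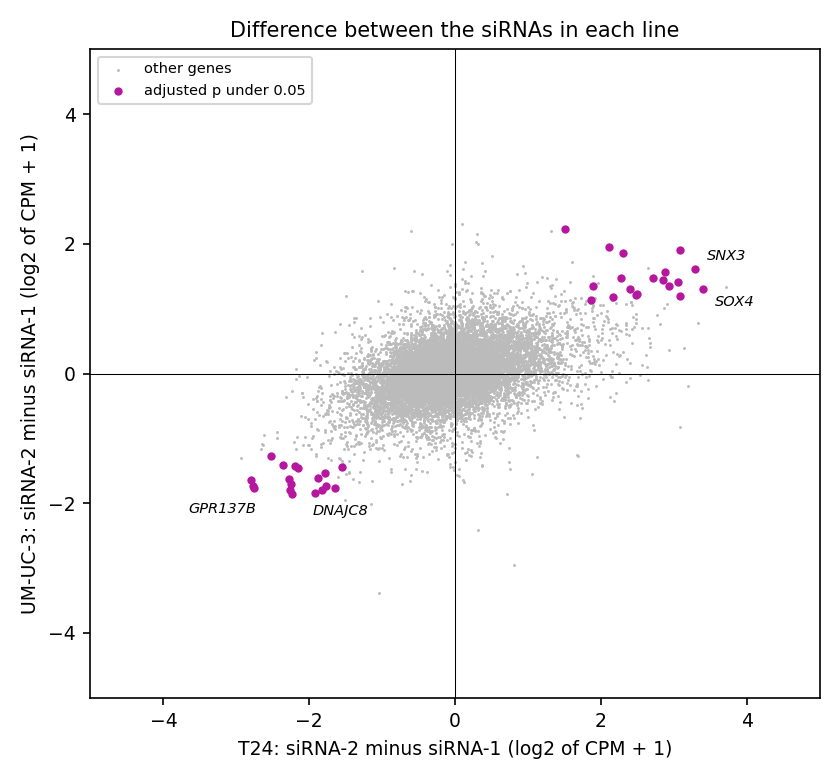
Difference of siRNA-2 minus siRNA-1 in log2(CPM + 1) in T24 (horizontal axis) and UM-UC-3 (vertical axis), with 1 point per gene. The 37 genes at an adjusted p under 0.05 are coloured, and the r across all 13265 genes is 0.417.

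The difference between the siRNAs, into which no control library enters, had an r of 0.417 and a rho of 0.391 between the lines across 13265 genes. Against the controls over both lines, siRNA-2 alone had 6 genes past the threshold, HSF1 (log2 fold change -2.03), CKS1B, a cell cycle kinase subunit (-2.24), SUMO3 (-1.94), CUTA (-1.90) and DNAJC8 (-1.78) lower and ARRDC3 (1.89) higher, each with an adjusted p of 0.0415 in limma-trend. siRNA-1 alone had 0, with 1948 genes at an unadjusted p under 0.05. Other tools were not run on these separate comparisons.

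Of the lists, 4 were called between the siRNAs. The PRMT5 and arginine methyltransferase list was lower with siRNA-2 (12 of 12 negative, median -0.36, adjusted p = 0.0125), as were the AP-1 list (-0.42, 0.0125) and the interferon list (-0.42, 0.0185), and hypoxia and glycolysis genes were higher (0.25, 0.045). Each had an adjusted p of 0.96 with an estimated correlation. Over all genes 1 member of the PRMT5 list passed, CLNS1A. Adjusted over the list alone 1 member passed in each of the PRMT5, AP-1 and interferon lists and 0 in the hypoxia list. The interferon list turned upward without T24 siRNA-2 (adjusted p = 0.874) and lost its call without UM-UC-3 siRNA-1 (0.313), the AP-1 call was lost without UM-UC-3 siRNA-1 (0.716), and the PRMT5 call without UM-UC-3 siRNA-2 (0.0848) or without genes with either 3' UTR word (0.0863). The hypoxia call was lost without T24 siRNA-2 (0.105), UM-UC-3 siRNA-1 (0.0707) or UM-UC-3 siRNA-2 (0.0559) and under quantile normalization (0.106). At a mean of at least 5 CPM the interferon (0.079) and hypoxia (0.0783) calls were lost. Without T24 siRNA-1 13 lists were called, and without T24 siRNA-2 or UM-UC-3 siRNA-2 7 each. Among lists not called, ribosomal proteins (median -0.06, mean 0.11), the proteasome (-0.01, 0.03) and epithelial genes (-0.02, 0.01) had a median and mean of opposite sign and an upward test, as had mesenchymal genes (0.03, -0.03). The p53 targets had both below 0 (-0.01, -0.02) and an upward test (0.91).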

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

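The tests of the siRNA-2 word, of the HSF1 transcripts, of the words in S phase and mitosis transcripts and of the correlation over genes with and without the words were chosen only after the result was seen. The siRNA effect differed between the lines in 15 gene lists, by the test of the difference itself at camera's preset correlation, and in 0 with an estimated correlation. The median difference in log2 fold change, UM-UC-3 minus T24, was 1.251 for the ATF4 list, 1.408 for the unfolded protein list, 0.96 for mitosis, 0.945 for interferon, 0.875 for mesenchymal genes, 1.176 for lymphangiogenesis, 0.704 for NF-kB targets, 0.558 for AP-1, 0.515 for recombination genes and 0.358 for S phase. It was -0.924 for mitochondrial DNA genes, -0.485 for the proteasome, -0.65 for the chaperonin CCT list, -0.252 for ribosomal proteins and -0.553 for the PRMT5 and arginine methyltransferase list.

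The ATF4, unfolded protein and interferon lists were lower in T24 and not in UM-UC-3. Scaling of the libraries is argued against as the whole cause, since after quantile normalization the median of the ATF4 list in T24 was -1.168. A trend with GC content or transcript length is argued against too, since the median was -1.118 with the trend removed. T24 had 1 control library, so the state of that culture, which may have been stressed or sensing foreign RNA, cannot be told apart from an effect of the siRNAs in T24 on these lists. A response of T24 to loss of HSF1 that UM-UC-3 lacks stays open as the biological hypothesis. The lines also differed in how much HSF1 was left, 19.1% and 21.3% of the control in T24 and 36.6% and 26.6% in UM-UC-3. Whether this plays a part was not tested. A second T24 control would show whether the first was typical, but would not separate loss of HSF1 from a general effect of siRNA treatment.

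The replication and mitosis lists were lower and the histone list higher in all 4 siRNA libraries. With the GC and length trend removed, the median of the S phase list over both lines was -0.829, which argues against that trend as the whole cause. Of 71 searched S phase and mitosis members 2 (2.8%) carry either siRNA's word in the 3' UTR, against 17.2% of all searched genes, which argues against direct action through these words on those lists, while leaving out carriers removed none of the 38 S phase members (median -0.822), so an indirect action, or any on the histones, stays open. More RNA without a poly(A) tail in the siRNA libraries could raise other such genes too. Yet 20 small structural RNA genes had a median of -0.288 (95% bootstrap interval over genes, not libraries, -0.375 to -0.135). Whether the library preparation kept these small RNAs as it kept histone mRNA is not known, so these values cannot decide this explanation. An effect of the loss of HSF1 on cell division, and a general effect of siRNA treatment on growth, were not tested and stay open, the latter also because it is not clear whether the controls received siRNA.

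The siRNAs differed at the same genes in both lines (r = 0.417), and a trend with GC content or length does not account for this, since r was 0.412 with the trend removed. Each siRNA may lower transcripts whose 3' UTR matches its own seed: the word most depleted with siRNA-1 in T24, GACAAGA, was the most depleted of 15718 words in UM-UC-3 too (shift of 1109 genes -0.13, random words -0.025 to 0.026), and so was GTACTTC with siRNA-2 (782 genes, -0.251, random words -0.033 to 0.028). The joined words GACAAGAA and GTACTTCA each occur 1 time in the coding sequence of an HSF1 transcript of 2142 bases, picked as the one of its 2 coding transcripts that holds both, at positions 1298 (CAGCGTAGCCTGCCTGGACAAGAATGAGCT) and 337 (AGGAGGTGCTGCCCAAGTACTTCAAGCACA), while 0.398% of 6527 coding transcripts of like length hold both. That share does not allow for the pick, and 149 of 13612 other genes with at least 2 coding transcripts (1.095%) have one that holds both. Of the 10073 searched genes (r = 0.47), the 1733 with either word had an r of 0.623 and the 8340 with neither 0.414, so the words do not account for all of the difference, and the siRNA sequences are not in the labels.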

How the results depend on the processing

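The tests with edgeR, DESeq2 and limma-voom on recovered reads, those that left out genes with either word, those of the siRNA number as a block within a line, and those of lists with that block, quantile normalization or a pseudocount of 0.1 were chosen only after the result was seen, and the others were planned. The design had named edgeR with TMM as the test for read counts, and only its use on recovered reads was chosen then. With DESeq2 the calls were 78 over both lines, 256 in T24, 3 in UM-UC-3, 31 for the difference between lines and 250 for siRNA-2 against siRNA-1, against 0, 0, 0, 0 and 37 with limma-trend, and HSF1 had -2.04. Leaving out 1 library in turn gave 0 over both lines each time, 0 to 447 in T24 and 0 to 485 for siRNA-2 against siRNA-1. The 37 calls became 0 with no filter, 0 with edgeR and TMM, 0 with edgeR and RLE, 22 with limma-voom and 17 without word genes. The called lists of all 5 comparisons became 0 with an estimated correlation and 0 with fry. The 4 lists between the siRNAs became 2 at a mean of at least 5 CPM and 5 to 13 without 1 library. The correlation between lines was 0.26 at a mean of at least 20 CPM, 0.363 for siRNA-1 and 0.213 for siRNA-2, and that within T24 0.559 at that mean. The WDR5 value turned to -0.012 without the T24 control (UM-UC-3 alone), and ranged from there to 0.465 without the UM-UC-3 control (T24 alone). The siRNA number is the only thing that pairs libraries across lines, in 2 pairs. With it as a block 0 genes passed over both lines (1782 at an unadjusted p under 0.05), 119 for the difference between lines (108 higher, 11 lower), 847 in T24 and 12 in UM-UC-3, and 13, 18, 18 and 13 lists were called in that order. The contrast of a line could not be fitted without its control. Where no cause is named, the cause was not tested. Of 46 values for single named genes 27 passed with DESeq2 and not with limma-trend, and 8 lost their call with edgeR. Depth limits low genes, since 1 read was worth 0.0351 to 0.0422 CPM.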

Other observations

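The test of the siRNA-2 word was chosen only after the result was seen. Of 23 autophagy and lysosome genes 18 were positive in UM-UC-3 (adjusted p = 0.00495, and adjusted p = 0.45 with an estimated correlation), a call lost without UM-UC-3 siRNA-1 (0.122). In T24 15 of 23 were positive (median 0.14, adjusted p = 0.457). CTSD, a lysosomal protease, stood at 38.6, 74.5 and 54.6 CPM in T24 control, siRNA-1 and siRNA-2 and at 23.4, 58.0 and 46.7 CPM in UM-UC-3, and ATG2A, which moves lipid to growing autophagosomes, at 46.7, 102 and 83.2 CPM and 27.4, 42.9 and 35.4 CPM. The membrane protein LAMP1 stood at 385, 532 and 507 CPM and 294, 374 and 370 CPM. None of these genes passed (adjusted p of 0.424 for CTSD and ATG2A and 0.551 for LAMP1 by limma-trend over both lines).

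EGFR, the epidermal growth factor receptor, stood at 674, 243 and 464 CPM in T24 and 168, 107 and 101 CPM in UM-UC-3 (log2 fold change over both lines -0.85 ± 0.28, SE, adjusted p = 0.424). The collagen receptor subunit ITGA1 stood at 16.6, 3.62 and 3.96 CPM and 8.44, 4.40 and 7.47 CPM, while ZYX, a focal adhesion protein, stood at 281, 340 and 523 CPM and 201, 307 and 331 CPM. The p53 targets went both ways, with TP53I3 at 10.2, 20.4 and 27.0 CPM in T24 and 15.7, 20.7 and 38.7 CPM in UM-UC-3, and the DNA damage gene GADD45A at 256.4, 61.2 and 96.5 CPM and 44.9, 34.2 and 35.1 CPM.

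Library by library, the 379 genes with GACAAGAA in the 3' UTR had a median log2 fold change of -0.38 in T24 siRNA-1 and -0.139 in UM-UC-3 siRNA-1, against -0.029 and 0.086 with siRNA-2. The 305 genes with GTACTTCA had -0.325 and -0.135 with siRNA-2 and 0.155 and 0.056 with siRNA-1. For comparison, the 8340 genes with neither 7-base word had 0.171 in T24 and 0.041 in UM-UC-3 with siRNA-1, and 0.082 and 0.042 with siRNA-2. The positive values of the GTACTTCA genes with siRNA-1 thus lay near those of genes with neither word. Of the called genes lower with siRNA-1 that were searched, 10 of 18 carry its word (10.9% of other genes), SNX3 and SOX4 among them and CCDC106 not. Of those lower with siRNA-2, 10 of 17 carry its word (7.7% of other genes), among them CLNS1A, XBP1, SUMO3, GPR137B and DNAJC8, and KDM1B, PLPBP and CUTA do not. Words and genes were both picked on the difference between the siRNAs, so these counts are not independent evidence. That the carriers could be lowered directly is a hypothesis in line with the shifts of -0.13 and -0.251 that were found in UM-UC-3 for words chosen in T24.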
